A study of Homo sapiens with 3 samples.

How the data were processed

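MYC occupancy was profiled by ChIP-Rx, chromatin immunoprecipitation and sequencing with chromatin of another species added as a reference, in parental U2OS cells, a human osteosarcoma line. Per the labels' protocols, U2OS cells and mouse NIH3T3 fibroblasts were crosslinked (10 min, 1% formaldehyde), mouse cells were added at 10%, chromatin was sheared to between 200 and 500 bp, and libraries were made from 5 ng of DNA with 9 PCR cycles. The series holds 2 libraries immunoprecipitated with an anti-MYC antibody and 1 input library, and the series design calls the IP libraries biological replicates.

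The values analysed are those of 1 peak list that the authors deposited. The submitters' processing notes name cutadapt, Bowtie2, SAMtools, Picard and MACS2 and the builds hg19, mm10 and hg38, with no versions, settings or roles. The name of the deposited list gives hg38. The list carries the authors' fold enrichment of IP over control at each summit, a linear ratio as MACS2 writes it. It also carries the authors' −log10 p-value and −log10 q-value at the summit, and a score that in the deposited list is nearly always 10 times the −log10 q-value without its decimals. Only the fold and the −log10 q-value were used to describe, rank or filter peaks. How the mouse reads entered the scaling, which input scaling was used, and whether the 2 IP libraries were pooled for peak calling are not given in the sources used here. No per-library values were analysed, so the depth is unknown and no replicate error could be computed for any value. Peaks and genes are not independent replicates, and every interval and p-value below describes peaks or genes within this 1 list and covers counting error only.

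Genes came from RefSeq on GRCh38.p14, restricted to chromosomes 1 to 22 and X, with 19974 protein-coding genes among 59098 genes of all classes. The table used gives the span of each gene without strand, transcripts or sequence. The tests had been planned on transcript starts. They were run on the start and end of each annotated gene instead, both called gene ends here, and a gene is called bound where a summit lay within 1000 bp of either end. A bound gene takes the values of its strongest peak by −log10 q-value, with ties settled by fold. Peaks over 5000 bp from the ends of every gene of any class are called distal. Planned tests of E-boxes and other motifs, of matched or CpG-stratified promoters, of signed distance along transcription and of 5′ ends alone need sequence or strand and were not run. An annotated span can reach beyond the promoter in use, so an active promoter inside a long span counts as not bound.

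The share of peaks at gene ends was compared with 1000 random placements on the same chromosome, between its first and last annotated gene, since assembly gaps were not used here. The test was two-sided, and 0.002 is the smallest p it can give. For 30 gene lists the bound share was compared with that of all other protein-coding genes by Fisher's exact test, two-sided, with a conditional odds ratio and its 95% interval. Small nucleolar RNA host genes were compared with the other long noncoding RNA genes. Among bound genes, the median log2 fold of list members was compared with that of bound genes outside the list by a two-sided permutation test with 100000 resamples, for lists with 5 or more bound members. The smallest p this test can give is 2e-05. Peaks per chromosome were compared with the number expected from protein-coding genes by a two-sided exact binomial test. P-values were adjusted by the Benjamini-Hochberg method within each family of tests, over the 30 lists, the 24 lists with a fold test, the 23 chromosomes or the 368 symbol families, with a threshold of 0.05. Shares carry Wilson 95% intervals.

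The groups, tests, gene lists, first set of other settings and the rule for named genes were fixed before the data were examined. The rule names the 15 protein-coding genes with the highest −log10 q-value, the 3 strongest bound members of each list, all members of the MYC and MAX network and of the circadian clock, the 5 strongest distal peaks, and the bound members, where 5 or fewer, of lists bound less often. Some clock genes that the rule names are not reported here. The lists are general knowledge and none was taken from these libraries. Of the 30 textbook MYC targets, 20 also stand in another list.

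Alternatives were windows of 500 and 5000 bp, the stronger 50% of peaks by −log10 q-value, a −log10 q-value of at least 10, any base of the peak in place of the summit, and −log10 q-value in place of fold. Members that share a peak were also counted once, and chromosomes were compared by annotated length and by gene-end peaks alone. Stratification by gene density (protein-coding genes within 100000 bp) and by gene length, each in 5 bins with the Cochran-Mantel-Haenszel test, was added after the data were seen, as were the comparisons between lists, symbol families, tRNA genes, peaks of 10-fold or more and the removal of gene families. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, numba 0.67.0 and matplotlib 3.10.9 were used. The scripts were tested on simulated data over the 19974 genes: 200 of 200 genes with placed peaks were recovered, 47 of 50 lists simulated at 80% bound were called, and 9 of 1400 unchanged lists were called. A shift of 0.5 log2 units in 50 genes was called in 95 of 100 simulations, and no shift in 2 of 100.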

Results

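MYC ChIP-Rx in parental U2OS cells, with 2 IP libraries and 1 input, is represented by 9818 peaks that cover 8.04 Mb of chromosomes 1 to 22 and X. In the authors' deposited list the median peak was 747 bp wide (quartiles 537 and 1009 bp), with a median fold enrichment over input of 7.78 (quartiles 5.58 and 11.5) and a median −log10 q of 47.8. All fold and −log10 q values of single peaks below are the authors' own, from that list, and have no replicate error. List members said to be strongest, highest or leading are so by −log10 q. Other members of the same list can have higher folds.

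MYC was concentrated at the ends of genes. Of the 9818 summits, 6387 (65.1%, 95% interval 64.1 to 66.0) lay within 1000 bp of an end of a protein-coding gene, and 2717 lay within 100 bp. Random placements put 2.87% of peaks there on average and at most 3.41% (two-sided permutation of positions, p = 0.002, the smallest the placements can give). Moving every summit by 10000 or 50000 bp to either side left 6.12% to 6.81% at gene ends. Another 665 summits lay at the end of a gene of another class, 1535 inside a protein-coding gene, 278 inside another gene and 953 between genes.

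**Figure D1:**
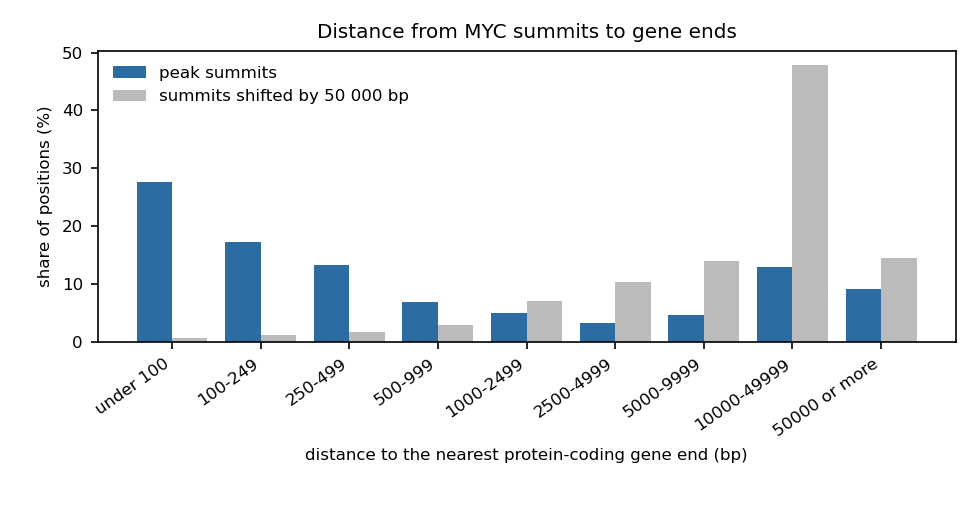
Share of MYC summits (blue) and of the same summits moved by 50000 bp (grey), in percent of the 9818 positions, by distance in bp to the nearest protein-coding gene end; the bins widen to the right. Summits are most frequent under 100 bp (27.7%, against 0.693% of moved summits).

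Peaks at gene ends were higher than distal peaks. The 6387 gene-end peaks had a median fold of 8.16 and the 1761 distal peaks (17.9%) one of 6.87, a difference of 0.25 log2 units (permutation test, p = 2e-05, the smallest the resamples can give). In the stronger 50% of peaks the difference was smaller, at 0.10 log2 units (permutation test, p = 0.00084). Of the 1761 distal peaks, 975 lay inside a protein-coding gene, so the distal class can hold promoters in use within longer annotated spans. At gene ends 51.7% of summits (50.4 to 52.9) lay on the inner side of the gene (exact binomial p = 0.0082), but in the stronger 50% of peaks the share was 49.8% (p = 0.787).

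The strongest peak of the list by −log10 q was a distal one. It lay on chromosome 7 from 4641437 to 4642640 (hg38), between genes and 40210 bp from the nearest end of any gene, that of FOXK1, a forkhead transcription factor, with a fold of 89.5 and a −log10 q of 2726. Whether this site is a promoter missing from the annotation, a repeat or an artefact of mapping was not analysed here, so its fold and distal class are given as listed. The next strongest distal peaks lay inside USP32, a deubiquitinase gene (chromosome 17, 60392120 to 60393449, fold 22.8, nearest protein-coding end that of CHCT1), and inside CLN6 (chromosome 15, 68228937 to 68230202, fold 45.8). Those inside AEN, a p53-induced nuclease gene (chromosome 15, 88620802 to 88621890, fold 25.8), and ING5, a chromatin reader gene (chromosome 2, 241701202 to 241702274, fold 35), followed. Whether the 4 sites inside genes are exonic, intronic or promoters in use within a longer annotated span was not analysed here. Their distal class is therefore also given as listed.

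At gene ends the highest −log10 q (2709) belonged to a peak between CCDC47, a membrane protein biogenesis factor, and DDX42, an RNA helicase (chromosome 17, 63773213 to 63774800, fold 64.8). A peak with a fold of 109 lay at SNHG7, a small nucleolar RNA host gene, and the overlapping LOC124900276 (chromosome 9, 136727468 to 136729038). It was followed by SLC33A2 (fold 53.4), RPSA, a component of the small ribosomal subunit (fold 94.7, chromosome 3, 39406329 to 39407475), and the pair SNX8 and EIF3B, the latter a translation initiation factor (fold 76.9). G6PC3, a glucose-6-phosphatase (fold 91.9), PCBP1, an RNA-binding protein that shares its peak with ASPRV1 (67.4), SNX5 and MGME1 (79.3), SEC14L1 (42.3), MCTS2 (75.9) and RPLP0, a protein of the large ribosomal subunit (46.5), complete the 15 highest genes. Of these 15, 5 were also among the 15 highest by fold.

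A MYC summit lay at an end of 7510 of 19974 protein-coding genes (37.6%, 36.9 to 38.3), and 2412 of the bound genes shared their strongest peak with a neighbour. Of the 10991 genes of at least 20000 bp, 4624 had a summit at 1 end only and 64 at both ends. Among the 12464 genes not called bound, 1289 had a summit elsewhere inside the annotated gene. With the stronger 50% of peaks alone, 4248 genes were bound.

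The protein synthesis machinery was bound far more often than other genes, and its peaks were high. Of cytosolic ribosomal protein genes 79 of 86 were bound (odds ratio 18.9, 95% interval 8.76 to 48.6, adjusted p = 4.56e-25, Fisher's exact test), led by RPSA, RPLP0 and RPL23A (fold 62.6). Their bound members had a median fold of 20.6 against 8.24 in other bound genes, 1.32 log2 units higher (permutation test, adjusted p = 9.6e-05). Ribosome biogenesis and nucleolar genes were bound in 57 of 64 cases (odds ratio 13.6, 6.19 to 35.4, adjusted p = 1.01e-16, Fisher's exact test), with a median fold of 19.7, among them the nucleolar GTPase gene GNL3 (40.1), the RNA helicase gene DDX21 (26.7) and WDR43 (98.9). Translation initiation and elongation factors followed with 46 of 54 (odds ratio 9.59, median fold 13.5), including EIF3B, EEF1A1 (78.5) and the helicase gene EIF4A1 (97.7). For aminoacyl-tRNA synthetases, which charge tRNAs, 18 of 20 were bound (odds ratio 15, median fold 16.9), with IARS1 (44.3), YARS1 (68.6) and GARS1 (46.9) strongest.

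Subunits and factors of RNA polymerases I and III, which make ribosomal RNA and tRNA, were bound in 26 of 31 cases (odds ratio 8.66, median fold 15.5), led by GTF3C2 (28.6), POLR3D (21.9) and GTF3C4 (19.1). Small nucleolar RNA host genes stood out among long noncoding RNA genes, with 21 of 30 bound against 10.9% of the rest (odds ratio 19.1, 8.37 to 47.4, adjusted p = 1.75e-13, Fisher's exact test) and a median fold of 25.7. SNHG7, SNHG20 (42.3, a peak shared with SEC14L1) and SNHG26 (59.5) were the strongest. The median folds of these 4 groups of translation factors, synthetases, polymerases and host genes were higher than those of other bound genes (permutation tests, adjusted p between 9.6e-05 and 0.00043), although translation factors no longer passed within the stronger 50% of peaks (adjusted p = 0.123).

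Mitochondrial ribosomal proteins were bound in 62 of 77 cases (odds ratio 6.91, 3.88 to 13.1, adjusted p = 1.3e-13), but at a median fold of 8.83 that did not differ from other bound genes (adjusted p = 0.593, permutation test), although their −log10 q did (0.62 log2 units, adjusted p = 0.013). MRPL15 (81.5), MRPL12 (27.6) and MRPS2 (43.1) were the strongest. Compared directly, bound cytosolic ribosomal protein genes had peaks 1.22 log2 units higher than mitochondrial ones (permutation p = 2e-05), while the bound shares of 91.9% and 80.5% did not pass after adjustment for 3 such comparisons (Fisher's exact p = 0.0403, adjusted p = 0.0722). In the stronger 50% of peaks the share did pass (78 against 49 bound, odds ratio 5.51, Fisher's exact test, adjusted p = 7.16e-05). A gene bound in that set has a peak with a −log10 q of at least 47.8, so this share also reflects peak height. The comparison of cytosolic with mitochondrial genes and that with DNA replication below were chosen after the list values had been seen.

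DNA replication genes had a bound share of 90%, beside 89.1% for ribosome biogenesis genes, but lower peaks. Of 40 members 36 were bound (odds ratio 15 against other genes, adjusted p = 2.7e-11, Fisher's exact test), and 31 with a window of 500 bp (odds ratio 7.01). Among the 36 were the replicative helicase genes MCM7 (fold 37.4), MCM4 (32.0) and MCM3 (15.5). Their median fold of 7.42 did not differ from that of other bound genes (permutation test, adjusted p = 0.391; lower in the stronger 50% of peaks, adjusted p = 0.0059). It lay 1.41 log2 units below that of ribosome biogenesis genes (permutation p = 2e-05), whereas the odds ratio of being bound between the lists was 0.906 (0.181 to 3.87, exact p = 1). In the stronger 50% of peaks that odds ratio was 5.99 (Fisher's exact test, adjusted p = 0.00011), with 20 replication genes and 55 ribosome biogenesis genes bound. As that set is chosen by −log10 q, this odds ratio too reflects peak height. Cell cycle regulators were bound in 24 of 33 cases (odds ratio 4.44, median fold 10.5), with the kinase genes AURKA (13.4), WEE1 (25.0) and CDK4 (16.5) strongest. CCND1, CDKN1A and RB1 were among the 9 not bound, and are named here after their values were seen. For them this means no summit within 1000 bp of an annotated end, which does not exclude a summit inside the gene.

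Biosynthetic genes were also bound more often. Nucleotide and one-carbon synthesis genes reached 24 of 32 (odds ratio 4.99, 2.17 to 12.9, adjusted p = 4.28e-05, Fisher's exact test) with a median fold of 20.2, led by NME1 (49.0), MTHFD1L (47.1) and PPAT, the first enzyme of purine synthesis (55.4). PAICS, a purine synthesis gene named here after its value was seen, did not count as bound. It is annotated on chromosome 4 from 56410507 to 56464578, across the end of PPAT at 56435615, with 1 summit inside it and the summit nearest to an end of it 3349 bp away. Chaperonin and heat shock genes reached 20 of 22 (odds ratio 16.6, median fold 17.5), with CCT5 (47.8) and the shared peak of HSPD1 and HSPE1 (33.5). Spliceosome genes reached 35 of 40 (odds ratio 11.7, median fold 13.4), with SNRPD1 (46.1), HNRNPA1 (36.7) and SRSF6 (69.6). The median folds of these 3 lists passed the permutation test (adjusted p between 9.6e-05 and 0.00062), but that of spliceosome genes did not in the stronger 50% of peaks (adjusted p = 0.269).

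Glycolysis genes were bound in 14 of 20 cases (odds ratio 3.88, 1.4 to 12.3, adjusted p = 0.0057, Fisher's exact test). ENO1 (fold 59.3), LDHB (53.1) and GAPDH (22.2) were highest by −log10 q. The median fold of bound members was 13.0 (adjusted p = 0.044, permutation test). With a window of 500 bp the odds ratio was 1.66 (Fisher's exact test, adjusted p = 0.365), and the fold difference passed neither with −log10 q in its place nor in the stronger 50% of peaks (permutation tests, adjusted p of 0.109 and 0.135). Proteasome subunits (29 of 39, odds ratio 4.83), respiratory complex I subunits (27 of 36, 4.99) and transcription elongation and pausing factors (27 of 30, 15) were bound more often (adjusted p between 9.48e-09 and 1.21e-05), at median folds of 9.29, 8.88 and 9.32 that did not differ from other bound genes. Their strongest members by −log10 q, with folds in brackets, were PSMD9 (31.8), PSMD14 (48.4) and PSMD3 (24.0), then NDUFS1 (26.7), NDUFB9 (14.0) and NDUFV2 (13.3), and TOP1 (25.1), XRN2 (31.5) and RTF1 (18.5). Cholesterol synthesis genes (14 of 22, odds ratio 2.91, Fisher's exact test, adjusted p = 0.0178) included LSS (19.1), the regulator gene SREBF1 (14.5) and SQLE (9.47), and their call was lost with either other window and in the stronger 50% of peaks (adjusted p between 0.0901 and 0.14).

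**Figure D2:**
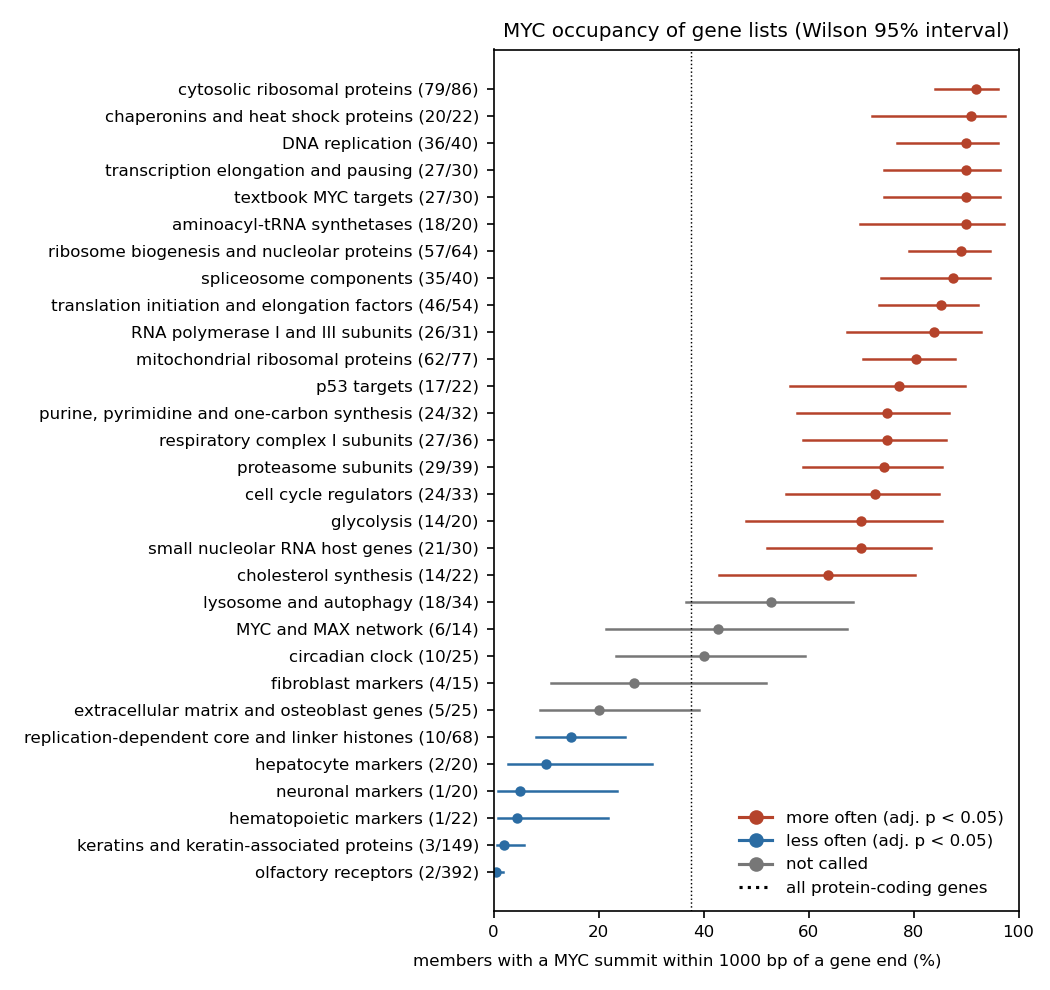
Percent of members of each of the 30 gene lists with a MYC summit within 1000 bp of a gene end (points, with bound and total members in brackets) and Wilson 95% intervals (lines); the dotted line is the 37.6% of all protein-coding genes. Red lists (19) were bound more often and blue lists (6) less often than other genes after adjustment, and grey lists (5) were not called; small nucleolar RNA host genes were compared with other long noncoding RNA genes.

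Textbook MYC targets were bound in 27 of 30 cases (odds ratio 15, 4.61 to 77.2, adjusted p = 9.48e-09, Fisher's exact test) with a median fold of 21. With windows of 500 and 5000 bp 22 and 29 were bound, at odds ratios of 5.59 and 37.0. NME1, EIF4A1 and GNL3 were strongest. Of the 3 not called bound, all named here after their values were seen, NPM1 and CCND2 had summits 1412 and 1313 bp from an end and the nearest summit to UBTF was 18401 bp away. Genes activated by p53 were bound in 17 of 22 cases (odds ratio 5.65, adjusted p = 0.00031) but with a median fold of 5.33, 0.64 log2 units below other bound genes (adjusted p = 0.0062, permutation test). PLK3 (fold 25.9), MDM2, the p53 ubiquitin ligase gene (12), and BAX (10.1) were the strongest bound members by −log10 q, though not the 3 highest by fold. AEN, also in this list, did not count as bound, although a distal peak with a fold of 25.8 lay inside it. The odds ratio of this list was 1.39 in the stronger 50% of peaks (Fisher's exact test, adjusted p = 0.459), and its lower fold passed neither there nor with −log10 q in place of fold (permutation tests, adjusted p of 0.793 and 0.109).

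Genes of the MYC and MAX network were bound in 6 of 14 cases, no more often than other genes (odds ratio 1.24, 0.356 to 4.09, adjusted p = 0.811, Fisher's exact test). The MAX partners MXD3 (fold 26.9), MXD1 (18.9), MGA (18.2) and MXD4 (4.84), the MLX partner MLXIP (18.7) and MAX itself (10.3) were bound, with a median fold of 18.4 (adjusted p = 0.0142, exceeding other bound genes by 1.15 log2 units in a permutation test, but adjusted p = 0.166 in the stronger 50% of peaks). MYC was not bound, and its ends lay 51633 bp from the nearest summit. MYCN, MYCL, MXI1, MNT, MLX, MLXIPL and ZBTB17 were not bound either, although MNT and ZBTB17 each had 1 summit inside the annotated gene.

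In the circadian clock list, whose core activators recognise related DNA elements, 10 of 25 genes were bound (odds ratio 1.11, 0.444 to 2.63, adjusted p = 0.838, Fisher's exact test). TIMELESS (fold 14.3), NR1D2 (12.7), DBP (8.63), CLOCK (13.0), PER3 (10.0), CSNK1D (9.55), NPAS2 (4.03), CRY1 (5.22), CRY2 (3.56) and BMAL2 (3.95) were bound. Of the 15 others, 6 had a summit between 1032 and 1398 bp from an end: BHLHE40, BHLHE41, PER1, NR1D1, RORB and CSNK1E. Among the rest, the ends of BMAL1, PER2, CIART, RORA, NFIL3, HLF and TEF lay farther from a summit. PER2, RORA, NFIL3 and TEF nevertheless each had 1 summit inside the annotated gene, while BMAL1, CIART and HLF had none. Counting any base of the peak gave an odds ratio of 2.75 (Fisher's exact test, adjusted p = 0.0164), and the direction turned with a window of 500 bp (0.953) and in the stronger 50% of peaks (0.705).

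**Figure D3:**
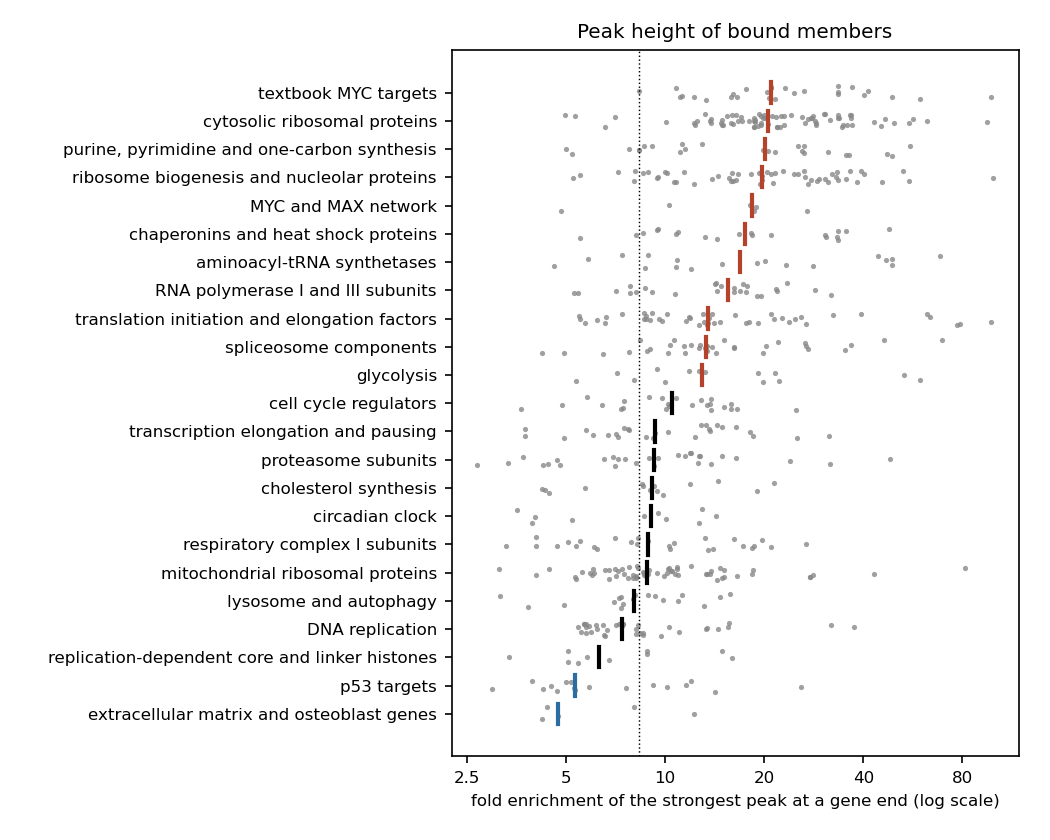
Fold enrichment over input (log axis, the authors' values) of the strongest gene-end peak of each bound member (grey points) for the protein-coding lists with 5 or more bound members, with the median of each list as a bar and the median of all bound protein-coding genes as a dotted line. Red and blue bars mark lists above and below other bound genes after adjustment: cytosolic ribosomal proteins have a median of 20.6 and p53 targets of 5.33.

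Lysosome and autophagy genes were bound in 18 of 34 cases (odds ratio 1.87, adjusted p = 0.0878, Fisher's exact test), led by ATP6V1D (14.7), LAMP1 (15.7) and ATP6V0D1 (13.1). The list passed with a window of 5000 bp (odds ratio 2.34, Fisher's exact test, adjusted p = 0.0277) and with any base of the peak (2.21, adjusted p = 0.0258). Extracellular matrix and osteoblast genes, which include markers of the bone lineage, were bound in 5 of 25 cases (odds ratio 0.415, Fisher's exact test, adjusted p = 0.107): VIM (12.2), COL5A2 (8.04), THBS1 (4.22), COL1A1 (4.4) and LOX (4.73). Their median fold of 4.73 lay below that of other bound genes (adjusted p = 0.0488, permutation test; 0.26 with −log10 q in its place), and with a window of 500 bp the list was bound less often (odds ratio 0.276, Fisher's exact test, adjusted p = 0.0388).

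Replication-dependent histone genes were bound in 10 of 68 cases (odds ratio 0.285, 0.13 to 0.563, adjusted p = 7.45e-05, Fisher's exact test), with H2BC5 (16.0), H4C11 (14.9) and H2BC12 (8.82) strongest. With a window of 500 bp 3 were bound (odds ratio 0.0931, adjusted p = 4.33e-08, Fisher's exact test). These genes are short, and with genes stratified by length the odds ratio was 0.520 and the list did not pass. Olfactory receptors were bound in 2 of 392 cases (odds ratio 0.00825), OR3A2 and OR1R1, which share 1 peak (14.5). Keratins and keratin-associated proteins were bound in 3 of 149 cases (0.0337): KRT80 (7.58) and the pair KRT8 and KRT18 (3.81). Both lists were below other genes (adjusted p of 5.25e-76 and 4.56e-25, Fisher's exact test).

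Markers of other cell types were rarely bound. Of hematopoietic markers 1 of 22 was bound, CD8A (fold 5.52, odds ratio 0.0789, adjusted p = 0.00088, Fisher's exact test), and of neuronal markers 1 of 20, TUBB3 (5.69, odds ratio 0.0872, adjusted p = 0.0024, Fisher's exact test). Hepatocyte markers were bound in 2 of 20 cases, TF (10.2) and TAT (4.15). Their odds ratio of 0.184 (adjusted p = 0.0123, Fisher's exact test) did not pass in the stronger 50% of peaks (0.195, adjusted p = 0.128). The summits lay outside these genes, 67 bp from an end of the 134644 bp span of TF and 520 bp from an end of TAT. Without strand it is unknown whether either end is a transcript start. Fibroblast markers, the cell type of the added mouse line, were bound in 4 of 15 cases, LOXL1 (8.83), SNAI2 (7.83), FBLN1 (5.81) and COL12A1 (4.29), which did not differ from other genes (odds ratio 0.603, adjusted p = 0.469, Fisher's exact test).

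Peaks were spread unevenly over the chromosomes relative to protein-coding genes. Chromosome X held 194 peaks, 0.465 times the expected 417 (exact binomial test, adjusted p = 9.43e-34), and chromosomes 21 (0.655), 19 (0.798), 11 (0.837) and 6 (0.896) also held fewer. Chromosomes 22 (1.32), 20 (1.27), 2 (1.24), 10 (1.2), 8 (1.18), 14 (1.14), 15 (1.13) and 3 (1.1) held more. Among the 3201 peaks of 10-fold enrichment or more, chromosomes X (0.640, adjusted p = 0.00014) and 19 (0.796, adjusted p = 0.0109) were below expectation and none was above it after adjustment (exact binomial tests), in a set with fewer peaks to test. With gene-end peaks alone the calls of 22 (1.04, adjusted p = 0.742), 20 (1.17, 0.0629), 8 (1.12, 0.144) and 15 (1.1, 0.265) ended (exact binomial tests), leaving 4 chromosomes that held more and 5 that held fewer. With annotated length as the expectation 8 held more and 10 fewer, and chromosomes 19 (3.00), 11 (1.22), 3 (0.9) and 8 (0.885) passed in the opposite direction. Leaving olfactory receptor, keratin, defensin and taste receptor genes, of which 0.818% were bound, out of the expectation ended the calls of 3 (1.08), 11 (0.945), 15 (1.11) and 21 (0.799), with adjusted p between 0.0951 and 0.258 (exact binomial tests).

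**Figure D4:**
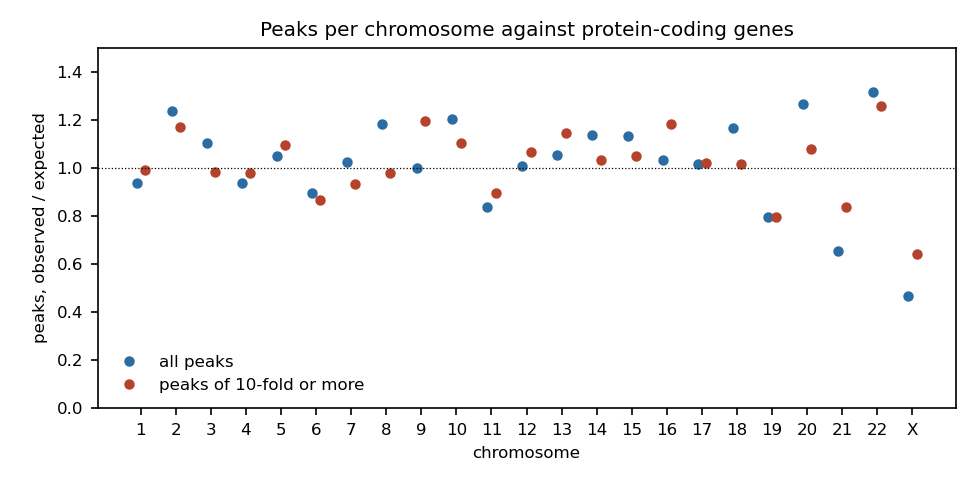
Number of peaks on each chromosome divided by the number expected from its protein-coding genes, for all 9818 peaks (blue) and the 3201 peaks of 10-fold enrichment or more (red); the dotted line marks 1. Chromosome X is lowest in both sets, at 0.465 and 0.640.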

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

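Over all alternatives, 291 values kept their direction and their side of the threshold or stayed within the range for counts, 17 no longer passed, 8 newly passed, 8 changed direction and 7 counts moved by more than 1.5 times; the causes were not tested unless stated. In the stronger 50% of peaks, 4248 genes were bound because fewer peaks entered, 9 lists differed in median fold, and 49.8% of summits lay inside the gene. In that set the odds ratios were 0.705 for clock genes, 2.12 for cholesterol synthesis, 1.39 for p53 targets and 0.195 for hepatocyte markers. Mitochondrial ribosomal protein and cholesterol synthesis genes there lay at −0.18 and −0.14 log2 units of other bound genes. A window of 500 bp gave odds ratios of 1.66 for glycolysis, 0.953 for clock genes, 2.03 for cholesterol synthesis and 0.276 for matrix genes, and 5000 bp gave 2.34 for lysosome genes and 2.23 for cholesterol synthesis. Any base of the peak gave 2.75 for clock genes and 2.21 for lysosome genes. With −log10 q in place of fold, clock genes lay at −0.40. Of the alternatives chosen after seeing the data, gene length strata gave 2.35 for cholesterol synthesis and 0.520 for histones. Ribosome biogenesis against DNA replication genes had odds ratios of 5.99 in the stronger 50% of peaks and 1.76 at 500 bp. Of 13 chromosomes that differed in peaks per gene, 9 passed with gene-end peaks alone (4 higher, 5 lower) and 2 among peaks of 10-fold or more. With annotated length as the expectation 18 differed (8 higher, 10 lower), 5 of them as before, 4 in the opposite direction, among them 19 (0.798 to 3.00) and 11 (0.837 to 1.22), and 9 newly. Without olfactory receptor, keratin, defensin, taste receptor and zinc finger genes 8 differed, 7 of them as before and chromosome 1 newly; with zinc finger genes kept 9 differed, all as before. Leaving out cancer-testis genes as well gave 10, with 1 new, and leaving out every family bound in under 5% gave 8, all as before. Without 5 unbound proteasome subunits the odds ratio of ribosome biogenesis genes against proteasome and complex I genes had to fall, and went from 2.74 to 2.03. It no longer passed unadjusted.

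The share of peaks at gene ends stayed between 58.2% and 73.3% under every window, threshold and overlap tried, above every random placement. Alternatives on the 5′ end, on CpG strata and on motifs were not run, for want of strand and sequence. With 1 list and no per-library values, no library could be left out. No paired analysis was possible because the input carries no replicate number and the list has no values per library.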

Other observations

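All tests in this part were chosen after the peak list had been seen, and none was planned. Grouped by the letters that open their symbols, 368 families of at least 8 protein-coding genes were tested against all other genes, and 60 were bound more often and 50 less often (Fisher's exact test, adjusted over families). Beyond the lists already described, RBM genes, which encode RNA-binding proteins (31 of 39), and CEP centrosomal proteins (29 of 39) were bound more often. NUP nucleoporins (19 of 23) and TRMT tRNA methyltransferases (14 of 16) were too. So were DDX helicases (29 of 37), of which DDX10, DDX18, DDX21 and DDX56 also stand in the ribosome biogenesis list. All 12 THAP zinc finger genes and all 11 COQ genes of ubiquinone synthesis were bound. ZNF genes were bound in 241 of 517 cases (odds ratio 1.46, Fisher's exact test, adjusted p = 0.00039). Genes with symbols that open with IL, interleukins and their receptors among them (9 of 85), were bound less often. So were collagens (COL, 4 of 44) and cytochromes P450 (CYP, 7 of 56). No member was bound among 31 CLEC lectins, 28 CCL chemokines and 23 CDH cadherins. In the stronger 50% of peaks the counts were 33 families above and 14 below.

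Outside protein-coding genes, a summit lay within 1000 bp of 79 of 443 tRNA genes (17.8%) against 2.37% of positions 10000 bp away, of 17 of 154 small nuclear RNA genes (11% against 2.27%), and of 94 of 1911 microRNA genes (4.92% against 1.78%). Pseudogenes were near summits less often than their surroundings (59 of 15212, 0.388% against 1.13%). All 4 passed Fisher's exact test with adjusted p between 4.75e-22 and 0.0002. Nearby tRNA genes can share a summit, so their test can count a summit more than once. Isolated tRNA genes are also counted by cluster below.

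Across the 23 chromosomes, which are not replicates, those with fewer peaks relative to expectation had higher median folds (Pearson r = −0.815, permutation p = 0.00016; Spearman rho = −0.709, p = 0.00028; without 21 and X, r = −0.486, p = 0.0274).

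The high bound share of the growth-related lists could reflect gene-rich neighbourhoods or short genes; stratified by gene density the median odds ratio of the 18 protein-coding lists bound more often was 9.14, and stratified by length 8.82, against 9.13 unstratified (small nucleolar RNA host genes not included), which argues against either as the whole cause. General activity of housekeeping promoters stays open for ribosome biogenesis genes. Against proteasome and complex I subunits the odds ratio was 2.74 (1.01 to 8.35, Fisher's exact p = 0.0481, adjusted p = 0.0722). Without the 5 proteasome subunits PSMA8, PSMB8, PSMB9, PSMB10 and PSMB11 it was 2.03 (0.702 to 6.4, Fisher's exact p = 0.163). None of these 5 was bound, so leaving them out could only lower the odds ratio, and this value decides nothing by itself. DNA replication (90%), transcription elongation (90%) and spliceosome genes (87.5%) had shares near the 89.1% of the list. In the stronger 50% of peaks the odds ratio without these 5 was 6.75 (Fisher's exact p = 1.89e-06). That set is chosen by −log10 q, which rose with fold over peaks (Spearman rho 0.883). The value therefore also measures peak height and is not separate evidence on the bound share. Peaks of bound ribosome biogenesis genes were 1.12 log2 units higher over all peaks (permutation p = 2e-05) and 0.68 in the stronger 50% (permutation p = 0.00176). Promoter CpG content and expression level were not analysed here and stay open, and with a single condition no other biological explanation was tested.

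Peaks at tRNA genes could belong to promoters of neighbouring genes. Among 199 tRNA genes over 5000 bp from the end of any other kind of gene, 18 had a summit within 1000 bp (9.05%) against 13 of 398 positions 10000 bp away (odds ratio 2.94, 1.33 to 6.68, Fisher's exact p = 0.0052). The 18 genes rest on 14 summits, so tRNA genes under 5000 bp apart were also counted as 1 cluster. Of 132 clusters 14 had a summit, against 7 of 264 positions (odds ratio 4.34, 1.59 to 13.0, Fisher's exact p = 0.00154). This argues against the annotated ends of neighbouring genes as the whole cause. Promoters in use inside longer annotated spans were not removed by the distance filter, so they stay open. The odds ratio of clusters was 7.06 with 500 bp, on 13 summits, and 5.59 in the stronger 50% of peaks, on 8 summits (1.31 to 33.3, Fisher's exact p = 0.00801). Reads shared between near-identical tRNA copies and signal from open chromatin were not tested and stay open.

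Uneven peak numbers per chromosome could come from DNA copy number, which differs between chromosomes in aneuploid lines such as U2OS, since weak sites on chromosomes with fewer copies may miss the threshold. Silent gene families as the whole cause are argued against for X, which lay at 0.465 with all genes and 0.512 without olfactory receptor, keratin, defensin, taste receptor and cancer-testis genes, the last with 103 members on X and none bound (exact binomial test, adjusted p = 4.93e-25). For autosomes they stay open in part, since 8 of 12 calls held without the first 4 of these families while those of 21 (0.655 to 0.799), 11 (0.837 to 0.945), 3 (1.1 to 1.08) and 15 (1.13 to 1.11) ended as the values moved towards 1. The SD of log2 observed over expected was 0.334 over all chromosomes and 0.238 over autosomes. Without the first 4 families it was 0.312 and 0.192, which argues against these families as the whole cause of the spread. The 0.306 with zinc finger genes left out too decides nothing, as 46.9% of these were bound and their peaks stayed. Among peaks of 10-fold or more, a set with fewer peaks, the SD was 0.220, between what copy number alone and its absence predicted. Chromosomes with fewer peaks also had higher median folds (r = −0.815 above), as a loss of weak peaks would give, but copy number was not analysed here. The effect of copy number therefore cannot be told apart from others. Silence of tissue-specific genes on X stays open too, since 13 of 16 growth-list genes on X and 511 of 608 on autosomes were bound (odds ratio 0.823, 0.22 to 4.59, Fisher's exact p = 0.73), against 18.2% and 38.5% of all genes.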
